A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

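Total RNA from the yeast strain labelled DBY4741, wild type or with REG1 replaced by a KanMX cassette (reg1), was compared on 4 spotted 2-colour arrays. Per the labels' protocols, cells grew at 28 °C in YPD, a rich glucose medium, RNA was purified with a column kit, and cDNA was primed with oligo(dT) and labelled indirectly with Cy3 and Cy5. Per the labels, reg1 RNA was in Cy5 on experiment 1 and in Cy3 on experiment 2 of the mutant comparison, and RNA of KOH-treated cells was in Cy3 on experiment 1 and in Cy5 on experiment 2 of the alkali comparison. The series' design text says that arrays of wild-type cells under alkali belong to another series. They were not analysed here.

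The authors deposited 1 table with a log ratio per row and array, taken here as log2. Per the labels, spots that were small or weak in both dyes were left out by the authors. The scanner, the background correction and the normalization are not given in the sources used here. The log base is not stated either and was taken as 2 from the values: the highest, 9.1, is a 549-fold ratio in base 2 and an 8955-fold ratio as a natural log, more than 16-bit intensities over the labels' minimum can give. The column medians were -0.028 and -0.068 for the mutant arrays and -0.120 and -0.040 for the alkali arrays, and values were used without further centring in the main tests. Between 16.5% and 23.6% of rows had no value on an array, and 4111 rows were measured on all 4. The signal over background of single spots is unknown, so no bound for weak spots is given. The arrays correlated positively within each comparison, so no sign was turned.

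Of the 6212 rows, 5662 were matched to a gene symbol by locus tag in a table of assembly R64, 23 of them after a change of letter case. The other 550 kept their names from the table. No gene had more than 1 row. No coordinates are given, since the table names no build.

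The register of the columns was checked from missing values only. For each row, the number of mutant arrays (0 to 2) that measured it was compared with the number of alkali arrays that measured the row 0 to 4 places above or below, and a dynamic programme chose the displacement along the table. It found 4 parts, and in 28 of 28 windows of 200 rows within 1 part the best of 9 displacements was that of the part. On simulated missing values for 6000 rows, 1 displacement made was found, 10 rows from its true place, and none was found where none was made. The 20 rows on each side of a change were therefore left out of the named results. Which columns were displaced was read from the ribosomal protein rows. This left 3159 rows with names borne out for the mutant and 5933 for alkali. In the realigned table the displaced mutant values were read 2 rows below their names, and the unresolved part was left out. This check and both reduced tables were chosen after seeing the data.

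Each comparison's mean log2 ratio was tested against 0 with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3), with all 4 arrays in 1 fit so that both comparisons share an estimate of the spread, over rows measured on both arrays of a comparison. The prior had 4.42 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. For named genes the adjustment ran over rows with names borne out. In the 2794 displaced rows the shared estimate of the spread of an alkali gene includes mutant values of another row. That of a mutant gene there includes alkali values of another row. Realigned, the alkali comparison had 2784 of 4521 genes called. Genes at 2-fold or more on both arrays were counted without a model.

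The 25 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists covered carbon metabolism, phosphate, cations, metals, stress, cell wall, ribosomes, amino acids, sterols, mating and the strain's marker genes. Lists with 5 or more measured members were tested two-sided with limma's cameraPR on the moderated statistics with a preset correlation of 0.01. This gave 22 lists for the mutant, of which 7 passed (8 of 23 as deposited), and 23 for alkali, of which 10 passed (10 as deposited). With a correlation estimated from residuals over genes of all 4 arrays in the realigned table, which leaves 2 residual degrees of freedom, no list passed in either comparison (lowest adjusted p = 0.136 and 0.239). Estimated correlations lay on both sides of the preset, for example -0.055 for sugar uptake and use and 0.228 for ribosome biogenesis. These adjusted p-values therefore reflect the few degrees of freedom as well as any correlation. The fry test, which asks whether a list's genes move 1 way on balance and does not compare the list with other genes, called 13 and 15 lists in that table. Named genes were REG1, the 12 largest called means of 1 sign on both arrays in each direction, and the 3 largest members of each list. Other members of lists, and genes of the overlap between comparisons, were named after their values were seen. Not every gene that the rule names is reported here. Ratios shared by several members of a list on 1 array were counted after the values were seen.

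The fit was tested on simulated ratios with the real missing values. Over 4903 rows of the mutant comparison it called 58 of 66 genes changed by 2 on the log2 scale, 24 of 67 changed by 1 and 2 of 67 changed by 0.5, with 3 unchanged genes called. Over 4719 rows of the alkali comparison it called 65 of 66, 22 of 67 and 1 of 67, with 5 unchanged genes called. Of 100 simulated lists of 20 genes shifted by 0.5, all 100 had p under 0.05 in each comparison. Of 100 without a shift, 4 (mutant) and 2 (alkali) did. Simulated values were drawn independently between genes, with 1 spread per gene over all 4 arrays. These counts therefore do not show error rates where list members correlate or the comparisons differ in spread. The alternatives tried were centring and scaling of arrays, a dye term, the experiment number as a block, each comparison's arrays alone, other filters on missing spots, robust eBayes, other fold thresholds, other list tests, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.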

Results

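Gene expression was measured in the budding yeast Saccharomyces cerevisiae on 4 spotted 2-colour arrays, each of which gives the ratio of 2 total RNA samples for 6212 rows named by open reading frame. Per the labels, the arrays ask what differs between a strain lacking REG1 and its wild type, and what alkalinisation of the medium changes in that mutant. REG1 encodes a regulatory subunit that directs the protein phosphatase Glc7 in glucose repression, the signalling by which glucose keeps genes for other carbon sources low. In the first comparison, 2 arrays set untreated reg1 cells against untreated wild-type cells. In the second, 2 arrays set reg1 cells given 16 mM KOH (to about pH 8) for 10 min against reg1 cells given 16 mM KCl, with medium at about pH 5.5 at the start. The dyes were swapped between the 2 arrays of each comparison. Each array measured between 4746 and 5190 of the rows, and 4903 rows of the mutant comparison and 4719 of the alkali comparison were measured on both arrays. With 2 arrays per comparison, the number of arrays limits the precision, and the labels do not say whether experiments 1 and 2 came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

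The 2 arrays of the mutant comparison correlated at r = 0.594 across rows, and those of the alkali comparison at r = 0.954, so values of the dye-swapped arrays already run in 1 direction. REG1 (YDR028C), the deleted gene, had a mean log2 ratio of -1.03 ± 0.10 (SD, n = 2) in the mutant, with -1.10 and -0.96 on the 2 arrays. This is 2.0-fold lower than in wild type and sets the direction as reg1 over wild type (adjusted p = 0.0209, limma). Since REG1 is replaced in the mutant, this ratio understates its loss. Whether other decreases are understated as well was not tested. REG1 was not measured on the alkali arrays. There the direction, KOH over KCl, is the likely one, from the titles and the order of the channels in the labels.

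The mutant and alkali columns do not name the same spots over the whole table. In the 3152 rows from YBR048W to YKL010C, the number of mutant arrays that measured a row correlated with the number of alkali arrays that measured it at r = 0.706. In the 2794 rows from YKL011C to YPR204W, 45.0% of the table, that correlation was 0.042, and it was 0.753 when the mutant columns were read 2 rows further down. In those rows the cytosolic ribosomal protein genes had a median log2 ratio of -0.17 in the mutant columns at their names and -0.55 when read 2 rows down, against -0.54 in the 3152 rows above. In the alkali columns their median was -1.66 at their names. In 199 rows from YAL067C to YBR047W the columns were displaced by 1 row (r = 0.830 against 0.206 at no displacement). Ribosomal protein medians there lean to the alkali columns, but 5 such rows do not settle which columns are at fault. Counts of rows below are given as deposited. Those from limma depend on the register too, since its estimate of the spread is shared between the columns of a row. Named genes and gene lists come from rows whose names this check bears out, 2524 measured on both arrays for the mutant and 4521 for alkali. Mutant values read at the shifted position are called realigned.

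**Figure D1:**
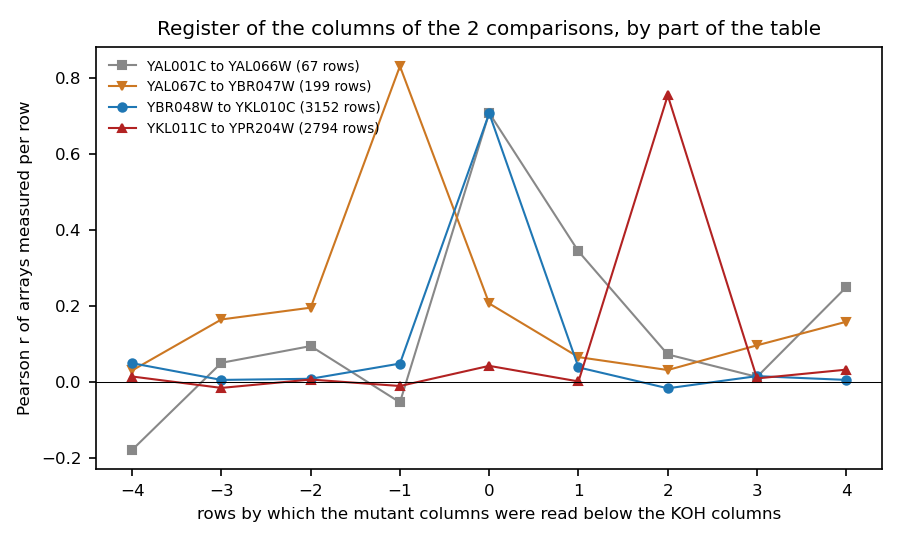
Pearson correlation (vertical axis) between the number of mutant arrays and the number of alkali arrays that measured a row, with the mutant columns read 0 to 4 rows above or below the alkali columns (horizontal axis), for 4 parts of the table. The 2794 rows from YKL011C peak at a displacement of 2 (r = 0.753) and the 3152 rows from YBR048W at 0 (r = 0.706).

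In the reg1 mutant, the largest increases were in genes of sugar use and of phosphate supply. SUC2 (YIL162W), which encodes invertase, had a log2 ratio of 4.43 ± 0.02 (SD, n = 2), 21.5-fold above wild type. The hexose transporter genes HXT7 (3.84 ± 0.81) and HXT4 (3.66 ± 0.37) and the hexokinase gene HXK1 (3.75 ± 0.21) rose as well. PHO89 (YBR296C), a sodium-coupled phosphate transporter gene, rose by 3.97 ± 0.01, and the acid phosphatase genes PHO5 (3.65 ± 0.53) and PHO12 (3.52 ± 0.03) by similar amounts. As measured, the decreases were smaller. WSC4, a cell-surface sensor gene, fell to -2.20 ± 0.03, the mannitol dehydrogenase gene DSF1 to -2.09 ± 0.75, and PAU5 to -1.95 ± 0.49.

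Over all rows as deposited, 404 of 4903 passed limma's test at an adjusted p of 0.05, 289 higher and 115 lower in the mutant. In the displaced rows the spread behind this count mixed values of different genes. Realigned, 325 of 4702 passed. Over the rows with names borne out, 215 of 2524 passed, 161 higher and 54 lower. At 2-fold or more on both arrays there were 146 higher and 34 lower rows, against 1 row that reached 2-fold in opposite directions. On experiment 1 alone it was 214 higher and 163 lower, and on experiment 2 alone 275 and 88. The remaining 5 of the 12 largest called increases were those of the maltose regulator and maltase genes MAL33 (2.87) and MAL32 (2.70), the transcription factor gene ADR1 (2.75), BSC1 (2.69) and HXT6 (2.44). The other named decreases included VBA3 (-1.67), FUS1 (-1.55), ATF2 (-1.46) and ARI1 (-1.37), together with PAU11 (-1.73), PAU12 (-1.66), PAU14 (-1.65), PAU24 (-1.55) and PAU1 (-1.54). HXT6 and HXT7, MAL12 and MAL32, and the PAU genes are near-identical copies whose spots may share signal. The 2 mutant arrays differed for several of these genes, for example 4.41 and 3.27 for HXT7, and -2.17 and -0.92 for FUS1. With the spread taken from the mutant arrays alone, 164 rows passed, as they did without either alkali array, while 266 passed without mutant experiment 1, 193 without mutant experiment 2, and 610 with a dye term. Without an alkali array the spread comes from the mutant arrays alone by construction, so that equal count is no separate result. The number of lower rows moved by a larger factor than that of higher ones in several fits, among them 280 higher and 71 lower after centring, 372 and 183 after scaling to the same spread, 374 and 236 with a dye term, and 134 and 30 with the mutant arrays alone.

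**Figure D2:**
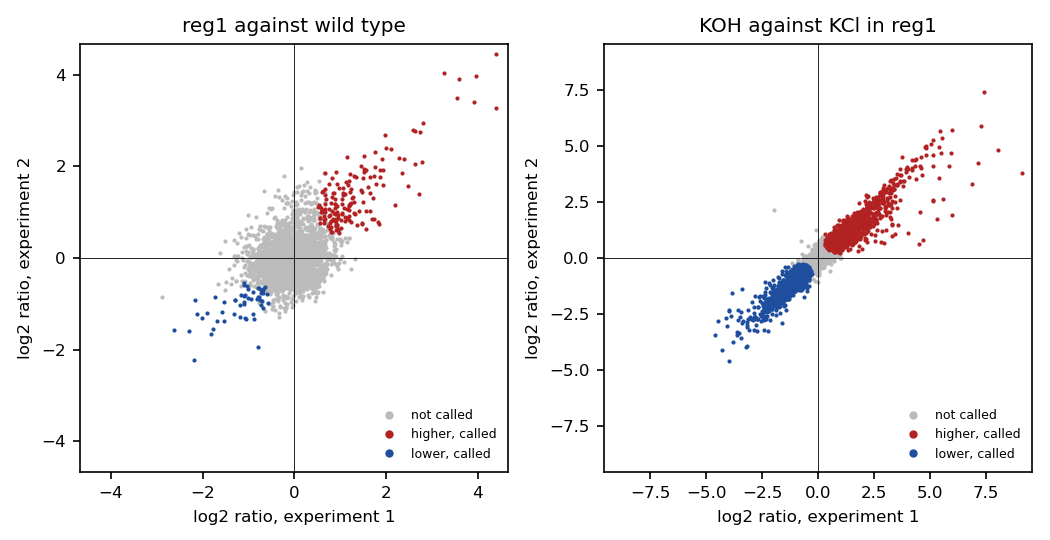
Log2 ratio on experiment 1 (horizontal axis) against experiment 2 (vertical axis) for each gene whose name is borne out, 2524 for reg1 against wild type and 4521 for KOH against KCl in reg1. Coloured points passed limma's test at an adjusted p of 0.05, 161 higher and 54 lower in the mutant and 1320 higher and 1501 lower after KOH.

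Glucose-repressed sugar uptake and use was the list with the lowest p in the mutant over rows with names borne out, and the phosphate regulon had the lowest realigned (9.4e-34 against 1.5e-31). Of 15 measured members 11 rose, 1 fell and 3 did not pass, with the same 11 and 1 when adjusted over the list alone (camera adjusted p = 5.0e-32, adjusted p = 0.136 with an estimated correlation). Besides the genes above, MAL12 (2.04), GLK1 (1.71), MAL31 (1.55), EMI2 (1.04) and HXT5 (1.01) rose, and HXT13 fell to -1.27. Both measured low-affinity glucose transporter genes rose, HXT3 with 2.06 ± 0.95 and HXT1 with 1.29 ± 0.62, a list too short to test. Among glucose signalling regulators, ADR1, the repressor genes MIG1 (1.33) and MIG2 (0.84) and the hexokinase gene HXK2 (1.34) rose, REG1 itself fell, and the other 11 of 16 did not pass. The test of that list did not pass either (camera adjusted p = 0.0577).

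The phosphate regulon list holds genes induced when phosphate is scarce, and also regulators and other phosphate genes that need not be. Of 14 measured members 11 rose and none fell, the same 11 when adjusted over the list alone (camera adjusted p = 4.4e-29, adjusted p = 0.136 with an estimated correlation). Besides PHO89, PHO5 and PHO12, the members SPL2 (2.24), PHO3 (2.03), the polyphosphate synthesis gene VTC1 (1.54) and the regulator gene PHO81 (1.46) rose, while PHO4, the pathway's transcription factor gene, had 0.07. PHO5 and PHO3 are close copies, as are PHO11 and PHO12.

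Most measured genes of oxidative phosphorylation rose. Of 15 oxidative phosphorylation genes 12 rose and none fell, with 14 and 1 when adjusted over the list alone, COX5B was at -0.74, and the list's median was 1.22 (camera adjusted p = 1.5e-12, adjusted p = 0.136 with an estimated correlation). Examples are the cytochrome bc1 genes QCR10 (1.87 ± 0.16) and QCR6 (1.70 ± 0.24) and the ATPase inhibitor gene INH1 (1.76 ± 0.03). Of 9 tricarboxylic acid cycle genes 5 rose and none fell, 7 when adjusted over the list alone, among them SDH4 (2.09) and LSC2 (2.03) (camera adjusted p = 2.5e-06, adjusted p = 0.224 with an estimated correlation). Glycolysis and fermentation had 1 of 14 members called, HXK2, and a median of 0.08 (camera adjusted p = 0.498). As deposited, with displaced rows included, this list passed as higher (camera adjusted p = 0.00429), and realigned it did not (0.411).

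Calcineurin targets and cation transport had 4 of 11 members up and none down, 7 up when adjusted over the list alone (camera adjusted p = 1.0e-04, adjusted p = 0.224 with an estimated correlation). They were GYP7 (1.89), the calmodulin-dependent kinase gene CMK1 (1.27), the glucan synthase gene GSC2 (1.16) and the calcium pump gene PMC1 (0.76). ENA2 had 0.08, and ENA1 was not measured on both mutant arrays. The cell wall and cell integrity list had 4 of 11 up and none down, 6 up and 1 down when adjusted over the list alone (camera adjusted p = 7.9e-04, adjusted p = 0.224 with an estimated correlation), namely PRM5 (1.44), GSC2, the kinase gene SLT2 (1.14) and SED1 (0.96).

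Cytosolic ribosomal protein genes were lower, with a median of -0.55 over 66 members (camera adjusted p = 2.0e-12, adjusted p = 0.224 with an estimated correlation). Of these 7 fell singly and 1 rose, and 50 fell when adjusted over the list alone. RPL29 (-0.96 ± 0.20) and RPS22A (-0.83 ± 0.29) were among the lowest. The member that rose, RPP1 (0.97), encodes a subunit of ribonuclease P and was taken into the list by its name only. The other lists did not pass over these rows. They include general stress response (4 up and 1 down of 15, camera adjusted p = 0.0577), mating and pheromone response (none up, FUS1 and BAR1 down, of 7, camera adjusted p = 0.0577), copper and iron homeostasis (3 up of 12, camera adjusted p = 0.113) and ribosome biogenesis (no member called of 29, camera adjusted p = 0.113).

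The remaining lists had few called members in the mutant. CIT2 (1.22) was the only one called of 7 in gluconeogenesis and C2 use (camera adjusted p = 0.113), GLC3 (1.81) of 9 in glycogen and trehalose (0.198) and FAA2 (1.72) of 5 in peroxisomal beta-oxidation (0.381), all higher. HSP30 (-1.11) was the only one called of 10 in the chaperone list (0.165) and MET13 (-0.92) of 12 sulfur and methionine genes (0.165), both lower. HSP30 encodes a stress protein of the plasma membrane and is not itself a chaperone. Amino acid biosynthesis had LYS12 (0.76) and SER3 (0.71) up and ARG4 (-1.06) and ARG5,6 down of 34 (0.623), and oxidative stress defence GND1 (1.11) and GTT1 (0.92) up of 13 (0.623). None was called of 10 vacuolar proton ATPase genes (0.545), 10 ergosterol genes (0.615), 4 Rim101 pathway genes and 1 marker gene of the strain, URA3 (0.91), the last 2 lists being too short to test.

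Realigned, the mutant columns gave 325 of 4702 genes called, 239 higher and 86 lower. This reading was chosen after seeing the data. The same rule for named genes then added HXT2 (4.29 ± 0.39), a high-affinity glucose transporter gene, ISF1 (3.30) and the phosphate transporter gene PHO84 (3.04 ± 0.44) to the increases. To the decreases it added VBA5 (-3.12), HSP32 (-2.94), HSP33 (-1.95), YNL034W (-1.90), ARG1 (-1.86), PAU21 (-1.82), YLL065W (-1.81) and THI12 (-1.78). Of 83 list members called over rows with names borne out, 11 no longer passed realigned, among them HXT1 (adjusted p = 0.0586), MIG2 (0.0633), BAR1 (0.0549), PMC1 (0.0518) and LYS12 (0.0574). All 7 lists above kept their direction and passed, but the realigned table also holds the rows on which they had passed. The ribosomal protein list had also served to choose which columns to shift. In all, 12 of 23 lists passed. The further ones were gluconeogenesis and C2 use (camera adjusted p = 0.00469), copper and iron homeostasis (0.00121), glycogen and trehalose (0.00518), glucose signalling regulators (0.0248) and, lower, ribosome biogenesis (0.0245). Adjusted p with an estimated correlation was 0.374, 0.420, 0.224, 0.374 and 0.520 in that order. The median of the glucose signalling list was -0.04, opposite in sign to its test.

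**Figure D3:**
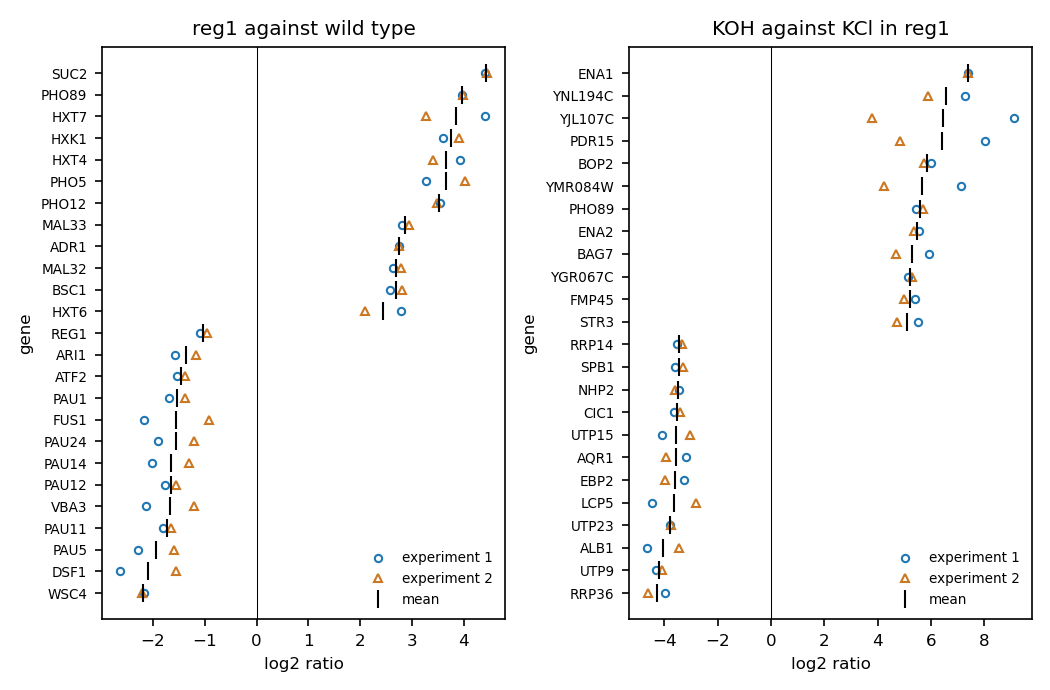
Log2 ratio (horizontal axis) on experiment 1 (circles) and experiment 2 (triangles) with their mean (bars) for REG1 and the 12 largest called increases and decreases of each comparison. The pairs for SUC2 (4.41 and 4.44) and ENA1 (7.40 and 7.40) nearly coincide, whereas those for PDR15 (8.04 and 4.83) lie apart.

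After 10 min at about pH 8, with ratios read as KOH over KCl, the sodium pump genes ENA1 and ENA2 were far higher. Storage carbohydrate genes were also higher in these reg1 cells, and genes for making ribosomes were lower. ENA1 (YDR040C), a sodium pump gene of the plasma membrane, had a log2 ratio of 7.40 ± 0.00 (SD, n = 2), 168.9-fold above KCl, and its neighbouring copy ENA2 5.46. ENA1 and ENA2 are near-identical copies whose spots may share signal. PHO89 rose by 5.57 ± 0.17 and the trehalose synthase subunit gene TSL1 by 4.71. The largest decreases were in genes of ribosome synthesis, RRP36 (-4.28 ± 0.45), UTP9 (-4.20 ± 0.14) and ALB1 (-4.04 ± 0.83).

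As deposited, 2968 of 4719 rows passed limma's test, 1396 higher and 1572 lower after KOH, and 2821 of the 4521 rows with names borne out, 1320 higher and 1501 lower. At 2-fold or more on both arrays there were 706 higher and 632 lower rows, against 1 in opposite directions. The other increases named by the rule were YNL194C (6.58), YJL107C (6.44), PDR15 (6.43), BOP2 (5.86), YMR084W (5.68), BAG7 (5.30), YGR067C (5.22), FMP45 (5.20) and STR3 (5.10). The 2 arrays differed most for YJL107C (SD 3.76), and gave 8.04 and 4.83 for PDR15 and 7.13 and 4.24 for YMR084W. The other decreases were UTP23 (-3.78), LCP5 (-3.64), EBP2 (-3.61), AQR1 (-3.56), UTP15 (-3.54), CIC1 (-3.52), NHP2 (-3.50), SPB1 (-3.45) and RRP14 (-3.43), most of them of ribosome assembly. With 1 alkali array left out, 1167 rows (without experiment 1, 604 higher and 563 lower) or 1300 rows (without experiment 2, 677 and 623) passed, so the larger share of lower rows did not hold. After centring it was 1476 higher and 1395 lower. With all arrays scaled to the same spread, 1287 passed, 750 higher and 537 lower.

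Of 117 cytosolic ribosomal protein genes 115 fell and none rose, with 115 down and 1 up when adjusted over the list alone (camera adjusted p = 5.4e-31, adjusted p = 0.239 with an estimated correlation). RPL29 (-2.98), RPL41A (-2.89) and RPS30B (-2.75) were lowest, and the list's median was -1.67. Of 51 ribosome biogenesis genes 45 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 6.5e-18, adjusted p = 0.272 with an estimated correlation). EBP2, CIC1, RRP14 and ENP1 (-3.08) led the list, and PWP2 (0.51) was the member that rose.

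Calcineurin targets and cation transport rose in 17 of 21 members and fell in 1, with 18 and 1 when adjusted over the list alone (camera adjusted p = 5.2e-18, adjusted p = 0.239 with an estimated correlation). Besides ENA1 and ENA2, PUN1 (4.40), GSC2 (4.35), the ammonium transporter gene MEP1 (4.21) and PMC1 (3.62) rose, and CNB1, the regulatory subunit of calcineurin, fell to -0.66. The cell wall and cell integrity list had 13 of 27 up and 2 down, the same when adjusted over the list alone, with the chitin synthase gene CHS1 (4.11) and the protease gene YPS1 (3.81) beside GSC2 (camera adjusted p = 2.7e-04, adjusted p = 0.272 with an estimated correlation). In the alkaline-responsive Rim101 list 8 of 10 rose, among them RIM8 (1.94 ± 0.97), NRG1 (1.66) and DFG16 (1.27), and ZPS1 fell to -0.75. The list's test did not pass (camera adjusted p = 0.113). It mixes components of the pathway with its targets, so these counts do not show the pathway's activity.

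Of 20 glycogen and trehalose genes 18 rose and none fell, the same when adjusted over the list alone, with a median of 2.85 (camera adjusted p = 1.1e-17, adjusted p = 0.239 with an estimated correlation). TSL1, GDB1 (4.31), the glycogen branching enzyme gene GLC3 (4.12) and the trehalose phosphatase gene TPS2 (3.68) are examples. General stress response genes rose in 22 of 29 and fell in 2, 24 and 2 when adjusted over the list alone, with XBP1 (4.02), MSC1 (3.89) and the vacuolar protease gene PRB1 (3.15) highest (camera adjusted p = 8.5e-09, adjusted p = 0.239 with an estimated correlation). Chaperones of the heat shock response went both ways, 3 up and 6 down of 18 (camera adjusted p = 0.699).

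Gluconeogenesis, glyoxylate cycle and C2 use rose in 15 of 20 and fell in 1, the same when adjusted over the list alone (camera adjusted p = 2.8e-07, adjusted p = 0.272 with an estimated correlation). The acetate transporter gene ADY2 (4.54), YAT2 (3.95) and the citrate synthase gene CIT2 (3.46) were highest, while the gluconeogenic enzyme genes FBP1 (-0.23) and PCK1 (0.06) did not pass and MDH2 (1.80) did. Sugar uptake and use had 8 of 17 up and 1 down, the same when adjusted over the list alone, led by HXT5 (4.86) and MPH2 (2.33), with HXT4 down (camera adjusted p = 0.0180, adjusted p = 0.272 with an estimated correlation). Without alkali experiment 2 the adjusted p of this list was 0.0662. SUC2 had 0.14 ± 0.30 and HXT7 -0.36 ± 0.30, and neither passed. Sulfur and methionine metabolism had 16 of 27 up and 2 down, the same when adjusted over the list alone, among them STR3, the methionine permease genes MUP3 (3.41) and MUP1 (2.89), and MMP1 (2.97) (camera adjusted p = 2.7e-06, adjusted p = 0.239 with an estimated correlation).

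The phosphate regulon had 8 of 17 up and 3 down, the same when adjusted over the list alone (camera adjusted p = 0.0478, adjusted p = 0.336 with an estimated correlation). PHO89, GDE1 (1.44) and PHO81 (1.43) rose, PHO3 fell to -1.68, and PHO5 had -0.57. This call ended with a dye term (0.143), with the replicate block (0.0736), over genes measured on at least 1 array (0.0651), and without alkali experiment 1 (0.09) or experiment 2 (0.131). As deposited its adjusted p was 0.05 when rounded. Oxidative phosphorylation had 18 of 28 down and 3 up, 19 and 3 when adjusted over the list alone, with ATP20 (-1.77) and QCR7 (-1.48) down and the external NADH dehydrogenase gene NDE2 (2.77) up, but the list's test did not pass (camera adjusted p = 0.0711). Amino acid biosynthesis went both ways, 14 up and 15 down of 47 (camera adjusted p = 0.354), with the arginine genes ARG3 (4.85) and CPA1 (2.13) up and LYS4 (-1.35) down. Ergosterol synthesis had 12 of 25 down and 2 up (camera adjusted p = 0.229), and the vacuolar proton ATPase 9 of 18 down and 4 up (camera adjusted p = 0.6). For the tricarboxylic acid cycle (5 up and 6 down of 20) and amino acid lists here, and for oxidative stress defence in the mutant, the median had the opposite sign of the mean and the test.

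Glucose signalling regulators had 8 of 19 up and 4 down after KOH, with SIP4 (5.06) and ADR1 (3.14) up and STD1 (-1.44) and MIG2 (-1.19) down (camera adjusted p = 0.0711). Copper and iron homeostasis had 11 of 30 up and 8 down, among them FRE5 (1.94) and ATX1 (-2.56) (0.699), and oxidative stress defence 7 of 24 up and 12 down, among them SKN7 (1.28) and TRX1 (-1.30) (0.548). Peroxisomal beta-oxidation had 4 of 12 up and 2 down (0.386), and mating and pheromone response 2 of 10 up and 2 down, with AGA1 (1.98) up and FAR1 (-0.90) down (0.973). Glycolysis and fermentation had PYK2 (2.30), PFK1 (1.12) and ADH5 (0.73) up and TPI1 (-0.89), GPM1 (-0.77) and 2 others down of 20 (0.896), of which TPI1 (adjusted p = 0.0568) and FBA1 (0.0641) no longer passed realigned. In all, 13 of 464 called list members no longer passed realigned. However, 10 of these 20, such as TDH3, ENO2, PGK1 and CDC19, had the same ratio of -0.31 on experiment 2, against 28 of all 4521 genes. How far these 10 moved, and the test of this list, cannot be read from such values. Neither of the 2 low-affinity glucose transporter genes measured passed, a list too short to test. Of 4 marker genes of the strain, MET17 (1.22) and LEU2 (1.07) passed with higher and HIS3 (-1.05) with lower values, a list too short to test. Strains of this background commonly lack these genes, so the values may not measure their expression.

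**Figure D4:**
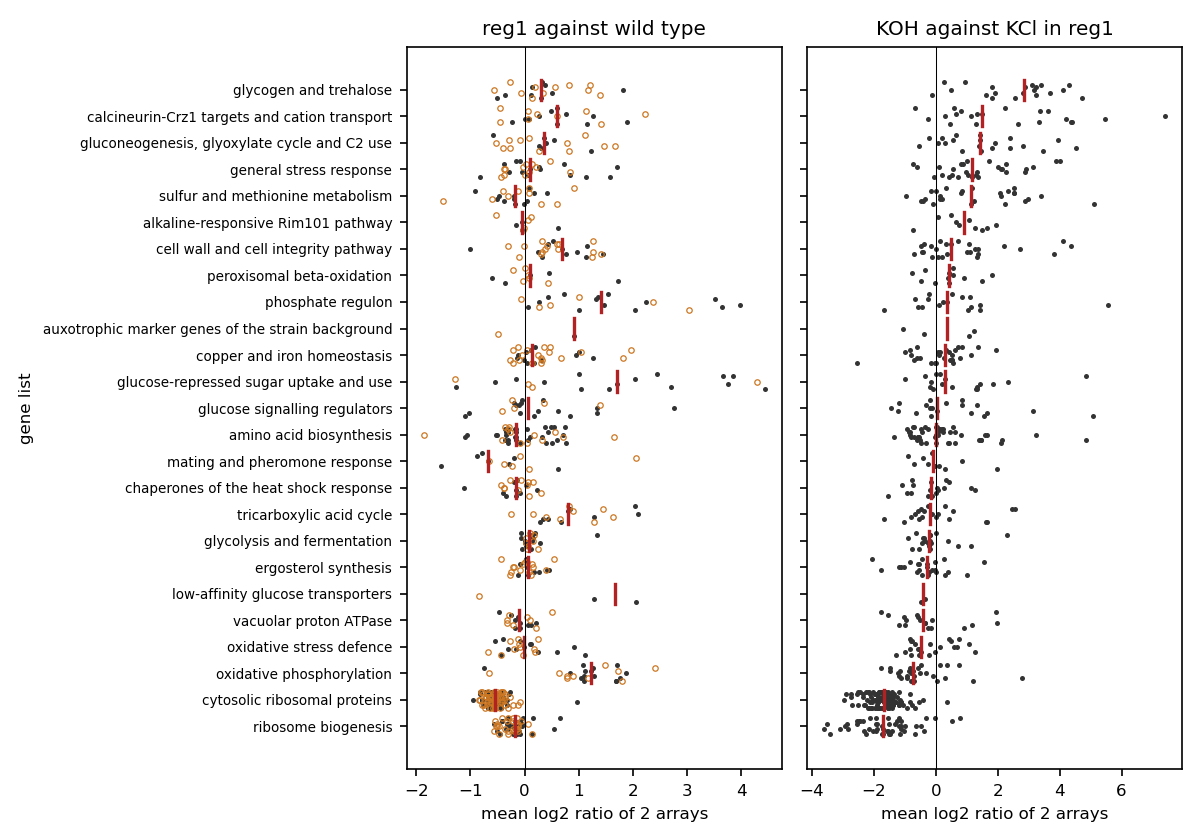
Mean log2 ratio of 2 arrays (horizontal axis) of each measured member of the 25 gene lists (rows), with names borne out (dark points) or realigned (open points), and the median of the former (bars). Ribosomal protein genes have medians of -0.55 in the mutant and -1.67 after KOH, and oxidative phosphorylation genes of 1.22 and -0.73.

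The mean log2 ratios of the 2 comparisons were positively related across the 2267 genes measured on all 4 arrays with names borne out (Pearson r = 0.33, Spearman rho = 0.41), as a description across genes, which are not independent replicates. The sign of this relation rests on the direction taken for the alkali ratio: turned, it would be an opposition, and shared increases would be genes lower after KOH. As deposited, over 4111 rows, r was 0.20 and rho 0.24, and realigned, over 4257 genes, r was 0.35. Of 70 genes at 2-fold or more above wild type in the mutant on both arrays, 25 were also 2-fold or more higher after KOH, against 9.4 by chance (Fisher's exact test, odds ratio 3.79, p = 1.5e-06, adjusted p = 5.9e-06 over 4 pairs of directions). PHO89, ADR1, the glutamate dehydrogenase gene GDH2 (2.33 in the mutant and 2.53 after KOH), GYP7, GLC3 (1.81 and 4.12) and PRB1 are among them. As deposited the overlap was 34 of 118 rows, against 16.8 by chance (adjusted p = 1.6e-04). Realigned, it was 53 of 127 genes against 17.3 by chance (adjusted p = 7.0e-15). Fisher's test takes genes as independent draws, which they are not. Its p-values, here and for opposite directions, are therefore a description across genes too.

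Some genes moved in opposite directions. Genes 2-fold or more higher in the mutant and lower after KOH numbered 7, against 9.1 by chance (adjusted p = 0.615), and realigned 8 of 127, fewer than the 17.5 by chance (odds ratio 0.41, adjusted p = 0.0162). They include the respiratory genes QCR6, QCR7, INH1 and TIM11 (1.17 and -1.55), and PHO3 (2.03 and -1.68). Realigned, 8 of the 18 genes 2-fold or more lower in the mutant were 2-fold or more higher after KOH, against 2.4 by chance (adjusted p = 0.00278). The proline use genes PUT4 (-1.54 and 4.33) and PUT1 (-1.14 and 3.55), the sulfate permease gene SUL2 (2.06 after KOH) and ARG1 (-1.86 and 1.59) are among these 8. Over the rows with names borne out it was 2 of 9 genes, against 1.2 by chance (adjusted p = 0.615).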

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

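The use of rows with names borne out and of realigned rows was chosen after seeing the data; the other alternatives were planned. Rows called in the mutant went from 404 to 610 with a dye term (over fewer rows), 164 with its own arrays alone and 215 over rows with names borne out, and ranged from 164 to 266 without 1 array. Rows called after KOH went from 2968 to 1287 with arrays scaled to the same spread, and ranged from 1167 to 3370 without 1 array. Where an arm kept 1 array, it was assumed to vary like the other comparison. Leaving out an array of the other comparison gives, by construction, the fit with a comparison's own arrays alone. The ends of these ranges at 164 and 3370 are therefore no separate results. At 2-fold on both arrays, the 180 mutant rows became 355 after scaling, 447 at 1.5-fold, 63 at 3-fold and 90 over rows with names borne out, and 363 to 377 on a single array, which drops the second condition. The 1338 alkali rows became 696 after scaling (441 higher and 255 lower, against 706 and 632), 2345 at 1.5-fold and 569 at 3-fold. The median absolute deviation was 0.314 on each mutant array, and 0.700 and 0.660 on the alkali arrays. Scaling to the same spread therefore enlarges mutant ratios and shrinks alkali ratios, which builds in the changes of the 2-fold counts. The cause of the changes in limma's calls with scaling and with the dye term was not tested. The dye term and the replicate block were fitted over rows as deposited. In displaced rows each such term was therefore shared by values of different genes, which limits these counts.

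With an estimated correlation 0 lists passed in either comparison, and fry, over rows as deposited and measured on all 4 arrays, called 12 mutant lists against 8 and 16 alkali lists against 10. The relation between comparisons, r = 0.20 as deposited, was 0.33 over rows with names borne out and 0.35 realigned, and 0.13 to 0.20 without 1 array. RIM101 in the mutant, at -0.04 and not called, was 0.00 after centring and 0.01 after scaling. The replicate block, with the experiment number as a block, gave 323 mutant and 2509 alkali rows, and 9 lists in each. Deviations of arrays with the same number correlated at -0.040 across 4111 rows (-0.094 realigned), but dye and number change together across the 4 arrays, so this value does not settle whether the numbers pair them. Of the calls of lists over rows with names borne out, the block ended 1, the phosphate regulon after KOH. The 7 mutant lists passed under every alternative fit run on the rows with names borne out and realigned. Of the 60 called among 86 named mutant genes, 22 lost their call with the mutant arrays alone, and of the 52 of them measured on all 4 arrays 13 lost it without mutant experiment 1 and 15 without experiment 2. Of the 88 called among 89 alkali genes, 9 lost it after scaling, and of the 67 of them measured on all 4 arrays 6 lost it without alkali experiment 1 and 4 without experiment 2. Testing each spot as its own row was not run, since no gene had 2 rows. Signal over background is unknown, so what it limits cannot be stated.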

Other observations

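The tests of the register at the largest displacement, of the smaller displaced part and of dye bias were chosen after the results were seen; the test on near-identical pairs was written before its result.

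The seripauperin (PAU) genes, a family of near-identical subtelomeric genes, formed a group that no list held and that was chosen after its values were seen. In the reg1 mutant all 10 members measured with names borne out lay below 0, with a median of -1.60 and a range of -1.95 to -0.56, and 7 of them fell. Realigned, 18 of 18 lay below 0 and 11 fell, with a median of -1.41. After KOH, 4 of 11 rose and 1 fell, with a median of 0.27. Their copies are close enough to share signal on spotted arrays, so they count as fewer than 18 separate measurements.

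In 45.0% of the table the values of the mutant columns do not go with their names. Different spots printed on the arrays of the 2 comparisons would leave no displacement at which the columns match, and this is argued against by a correlation of 0.753 at a displacement of 2. A displacement of rows when the table was put together is a candidate explanation, with that same value of 0.753 against 0.042 at no displacement. In 23 of 24 near-identical gene pairs split between the parts (95.8%), the mutant value of the displaced partner was closer to its copy when read 2 rows down. This held for 5 of 5 pairs outside the ribosomal protein genes, such as TEF1 (0.10 read 2 rows down and -0.23 at its name, with TEF2 at 0.13). The 19 ribosomal pairs overlap with the medians used to choose which columns were displaced. For the 199 rows of chromosomes I and II, the ribosomal protein median of the mutant columns was lowest at their names (-0.59). That of the alkali columns was -0.86 at their names, -1.74 read 1 row down and -1.91 read 2 rows down, the last from 2 measured rows. These values lean to displacement of the alkali columns, but it stays open, since that part holds 5 ribosomal protein rows. No biological explanation was tested.

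The 2 mutant arrays differed more from each other than the 2 alkali arrays, with an SD of the difference of 0.526 against 0.391 on the log2 scale. Dye bias of single genes common to both comparisons would make arrays with the same dye on the test RNA deviate together. Their deviations correlated at 0.065 across 2267 genes with names borne out. Arrays with the same dye always had the other experiment number, so effects of dye and of experiment would cancel in this value and cannot be told apart. Dye bias stays open, as do separate cultures and labelling of single arrays, which were not tested.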
